A study of Mus musculus with 2 samples.

How the data were processed

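The series compared RNA from the pancreas of mice homozygous for a mutant Glis3 allele (written Glis3zf/zf in the labels and named Glis3KO there) with RNA from wild-type pancreas, both at postnatal day 3. Per the labels, RNA of 2 pups was pooled for each genotype, 500 ng of total RNA was amplified and labelled with Cy3 or Cy5, and 750 ng of each labelled cRNA was hybridised for 17 hours to an Agilent whole mouse genome oligonucleotide array. The same pair of pools was run on 2 arrays with the dyes exchanged. The array labelled Glis3KO in Cy5 carried the wild type in Cy3, and the array labelled Glis3KO in Cy3 carried the wild type in Cy5. The arrays are a technical dye swap, so each genotype has 1 sample. There is no biological replicate, no test was made and no p-value was computed across genes.

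The deposited scanner files hold, per the file headers, the mean spot intensity and the median local background intensity of each channel on a linear scale, not normalised. They also hold processed intensity values, which per the file headers were background-subtracted with spatial detrending and dye-normalised by the scanner software, and a log10 ratio of Cy5 over Cy3 made from them. Per the file headers, a p-value of each log10 ratio comes from the software's error model of a single array. It describes spot noise and is not a test between genotypes. Per the labels, the software was Feature Extraction version 7.5 with default settings, followed by Rosetta Resolver version 6.0, whereas the file headers record module version 8.5.1.1. Which of these versions made the deposited values is not settled here. The deposited series table holds log2 ratios. It has 41185 rows, of which 41174 match a probe. Set against the scanner files, its columns equal the software's ratio of mutant over wild type within 0.002 log2 for 99.99% and 99.98% of probes on the 2 arrays, each with a median of 0. Its scale, centring and direction were settled by that comparison.

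Signals were processed from the mean and background intensities with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8). The background was corrected by the normexp method with an offset of 50, which keeps dim spots from giving extreme ratios and shrinks their folds. Ratios were normalised by loess within each array, with control spots at weight 0. Spots flagged as outliers were left out, 15 on the array with the mutant in Cy5 and 53 on the other, and saturated spots were kept. Spots of the same probe were averaged, both arrays were turned to mutant over wild type, and their mean was taken, so that a dye effect cancels. Loess assumes that most genes do not change at any intensity. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

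Each array had 41534 spots for genes and 2256 control spots, of which 314 were negative controls. The median mean signal was 265 in Cy3 (wild type) and 208.2 in Cy5 (mutant) on the first array, and 209.7 in Cy3 (mutant) and 207 in Cy5 (wild type) on the second. The median local background lay between 46.5 and 50. Between 94% and 96.8% of spots were well above background by the software's flag. The 95th percentile of the negative controls lay between 60.8 and 76.2, and filtering at it, chosen after seeing the data, left the calls at 38 higher and 25 lower. Between 26 and 48 spots per channel were saturated. The number of arrays limits the precision of every value.

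Probes were named through the RefSeq gene table of assembly GRCm38.p6, used for names and gene order only. Of 41174 probes, 22072 were named by their accession, 135 by another RefSeq accession of the probe, 606 by the symbol in the description and 516 by an older symbol, leaving 17845 without a gene name here. Each gene was read from its brightest unsaturated probe, or its brightest probe where all were saturated. This gave 16772 genes, and 16515 were well above background in the channel of at least 1 genotype on both arrays. Probe coordinates are those of the files, and their genome build is not given in the sources used here.

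A gene was called higher or lower by a rule of size: a mean change of at least 2-fold with at least 1.5-fold in the same direction on each array. Gene lists were described by the median log2 ratio of their measured members, leaving out members saturated in both genotypes on both arrays. That median was placed among those of 10000 random lists of the same size matched on intensity in 10 classes. This placing describes these 2 pools and is not a test of genotype. Among genes not past the rule of size, the brightest class ran from 10.8 to 16.0 log2. Very bright genes, several hormone genes among them, are therefore matched only coarsely. A gene saturated in a genotype on both arrays has only a bound, given as "at least", from normalised channel signals after loess and Aquantile, with the saturated spot at its value. Named genes were Glis3, the measured islet hormones, the members of the endocrine transcription factor and beta cell lists past the rule of size, up to 4 passing members of every other list (or up to 2 with the largest ratios where none passed), and the 12 largest rises and 12 largest falls with an official-style symbol. Further members of the hormone, transcription factor and beta cell lists are named where a sentence needs them to say what did not pass. The rule of size, the 25 lists, the rule for named genes and the alternatives were fixed before the data were examined. Lists of skeletal, cardiac and smooth muscle genes were drawn up once the data had been seen, as were the filter on negative controls and the count without skeletal muscle genes. Some genes named outside the rule are said to be so where they appear. Others are not marked there, among them Reg1, Reg3d, Reg4, Myh4, Sln and the saturated acinar genes given as examples. Some single genes of the lists are not reported here.

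The steps were tested on simulated data with the observed difference between arrays as noise. Among 16515 simulated genes of the comparison of mutant with wild type, the rule of size passed 0.1% of 1.5-fold changes, 99.8% of 2.5-fold changes and 100.0% of 4-fold changes. In 100 simulations without any change, it passed 0 genes. This noise is that of the arrays alone and leaves out differences between pups. Alternatives tried were no background correction, the software's own ratios, a normexp offset of 0, median centring, loess followed by Aquantile, other filters on dim and saturated probes, the median over a gene's probes, each array alone (which is also the value within each slide), the deposited series table and other thresholds.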

Results

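Gene expression was measured in the pancreas of newborn mice with a mutant Glis3 gene and of wild-type mice. Glis3 encodes a Krüppel-like zinc finger transcription factor, and the series was made to ask what it does in the development of the insulin-producing beta cells of the pancreatic islets. RNA of 2 pups per genotype was pooled at postnatal day 3, and both pools were hybridised together on 2 two-colour arrays with the dyes exchanged. There is thus 1 sample per genotype. The spread given below is that between the 2 arrays, and no value has a check across animals. Ratios are log2 of mutant over wild type, as the mean of the 2 arrays, so a negative value is lower in the mutant.

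The ratios of the 2 arrays correlated across 16515 detected genes with Pearson's r = 0.72 and Spearman's rho = 0.43 once both were turned to mutant over wild type. Genes are not independent replicates, and the correlation measures technical repeatability. The technical SD of a gene's mean ratio, taken from the difference between the arrays, was 0.08 log2 over the genes that did not pass the rule of size. By intensity it ranged from 0.066 in the dimmest of 10 intensity classes to 0.104 in the brightest. Most genes differed little, and 94.7% had a mean ratio within 0.3 log2 of 0. By the rule of size, 38 genes were higher and 25 were lower in the mutant pool. The mean ratios of these 63 genes varied between the arrays by a median of 0.06 log2 on each side of the mean, and by 0.59 at most, for Ins2. Of the 38 genes, 23 belong to a list of skeletal muscle genes drawn up once the rises had been seen, and 15 were higher without that list. With the scanner software's own ratios, 50 genes were higher and 44 lower, and with a normexp offset of 0 it was 49 and 42.

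**Figure D1:**
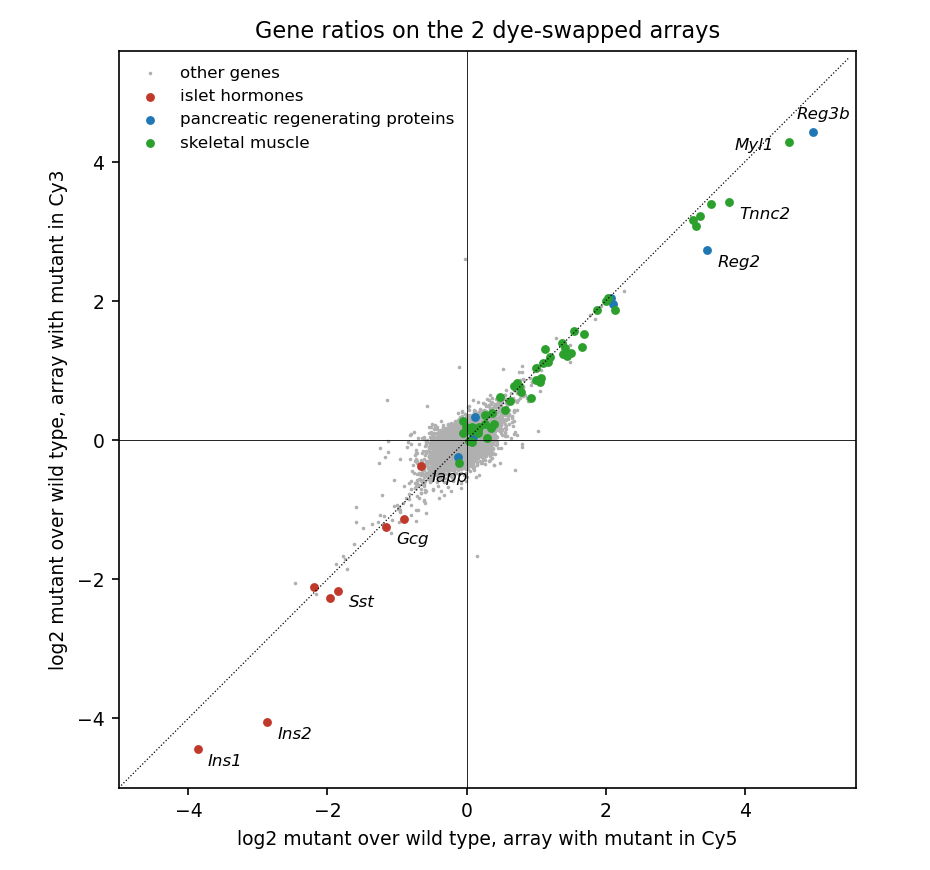
Each point is a detected gene, with its log2 ratio of mutant over wild type on the array with the mutant in Cy5 (horizontal axis) and on the array with the mutant in Cy3 (vertical axis). Members of 3 gene lists are coloured, the dotted line marks equal values, and Ins1 and Ins2 lie at the lower left and Reg3b and Myl1 at the upper right on both arrays. Ins2 was saturated in the wild type on both arrays and Ins1 on 1 array.

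The targeted gene was read by a single probe (Glis3, NM_175459), placed by the files on chromosome 19 from 27594259 to 27597792, a span of 3534 bp that is longer than a probe and so crosses a gap such as an intron. Its ratio was -0.02 with the mutant in Cy5 and 0.01 with the mutant in Cy3. Its mean raw signal was 121.3 in the mutant and 135.3 in the wild type, where the median local background lay between 46.5 and 50. Where the probe lies relative to the mutated part of the gene is not given in the sources used here. It therefore does not check the genotype labels.

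The genes for islet hormones were lower in the mutant pool. Of the 8 measured, 7 passed the rule of size and all 8 were below 0 on both arrays. The 2 insulin genes showed the largest falls on the arrays. Ins1 (NM_008386; chromosome 19, 51832487 to 51832546) was 17.8-fold lower as the mean of a ratio of -3.87 on the array where it was not saturated and of -4.44 on the array where its wild-type signal was saturated. Ins2 (NM_008387; chromosome 7, 137091790 to 137091849) was saturated in the wild type on both arrays and was at least 11-fold lower, with ratios of -2.87 and -4.05. Ppy, the pancreatic polypeptide gene, was 4.45-fold lower, Ghrl, the ghrelin gene, 4.34-fold lower, and Sst, the somatostatin gene of delta cells, 4.0-fold lower. Gcg, the glucagon gene of alpha cells, was 2.31-fold lower, with ratios of -1.16 and -1.25. Pyy, the peptide YY gene, was 2.02-fold lower, and with the mutant in Cy5 alone its ratio was -0.89, under 2-fold. Iapp, which encodes the amyloid polypeptide released with insulin, did not pass, with ratios of -0.66 and -0.37. The median of the list was -2.06, below all 10000 random lists matched on intensity. The skeletal muscle list stood at 0.93 in the same comparison, and the 14 acinar genes not saturated in both genotypes on both arrays at -0.06.

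Genes of beta cell function were lower in part. Of 21 measured members, 5 passed the rule and all 5 were lower. G6pc2, the islet glucose-6-phosphatase, was 4.56-fold lower, Abcc8, the sulfonylurea receptor subunit of the beta cell potassium channel, 3.44-fold lower, and Cltrn, which encodes the membrane protein collectrin, 2.42-fold lower, though with the mutant in Cy3 alone its ratio was -0.96, under 2-fold. Sytl4, which encodes the granule protein granuphilin, was 2.31-fold lower. Pcsk2, a prohormone convertase, was 2.11-fold lower, though with the mutant in Cy5 alone its ratio was -0.98, under 2-fold. The remaining 16 did not pass. Gjd2, the connexin of beta cell junctions, had a ratio of -0.996, just short of the rule, Slc30a8, the granule zinc transporter, -0.51, Pcsk1 -0.50 and Slc2a2, the glucose transporter, -0.17. The other detected probe of Pcsk1 gave -0.09 and that of Slc2a2 -0.76. The median of the list was -0.22, also below all 10000 random lists, and -0.33 with the mutant in Cy5 alone. The other detected probe of Abcc8 gave 0.25 and that of Pcsk2 -0.26. With the median over probes, both genes and Pyy no longer passed the rule.

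Genes of the neuroendocrine secretory granule had a median of -0.42 over 14 measured members, below all random lists. Chga, which encodes the granule protein chromogranin A, was 3.31-fold lower, and Scgn, the calcium sensor secretagogin, 2.20-fold lower. The other 12 members did not pass, and Chgb, the chromogranin B gene, which was named after its values were seen, had a positive ratio of 0.33. None of the 21 endocrine transcription factors passed the rule. Their median was -0.20, below all random lists, and 16 of them were below 0 on both arrays. Isl1 had the largest ratio, at -0.99. Nkx6-1 had -0.54, Neurod1 -0.53, Pax6 -0.30 (0.05 by its other detected probe), Pdx1, a master regulator of pancreas and beta cells, -0.14, Neurog3, which starts the endocrine programme, -0.02, and Mafa, a regulator of mature beta cells, -0.02. A further probe described as a Pax6 product, without a gene name here and so in no list, passed the rule at -1.39. It was named after its values were seen. The mean raw signals of Mafa were 79.3 and 84.9 in the 2 pools, close to those of negative control spots, which leaves little room to measure a fall.

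**Figure D2:**
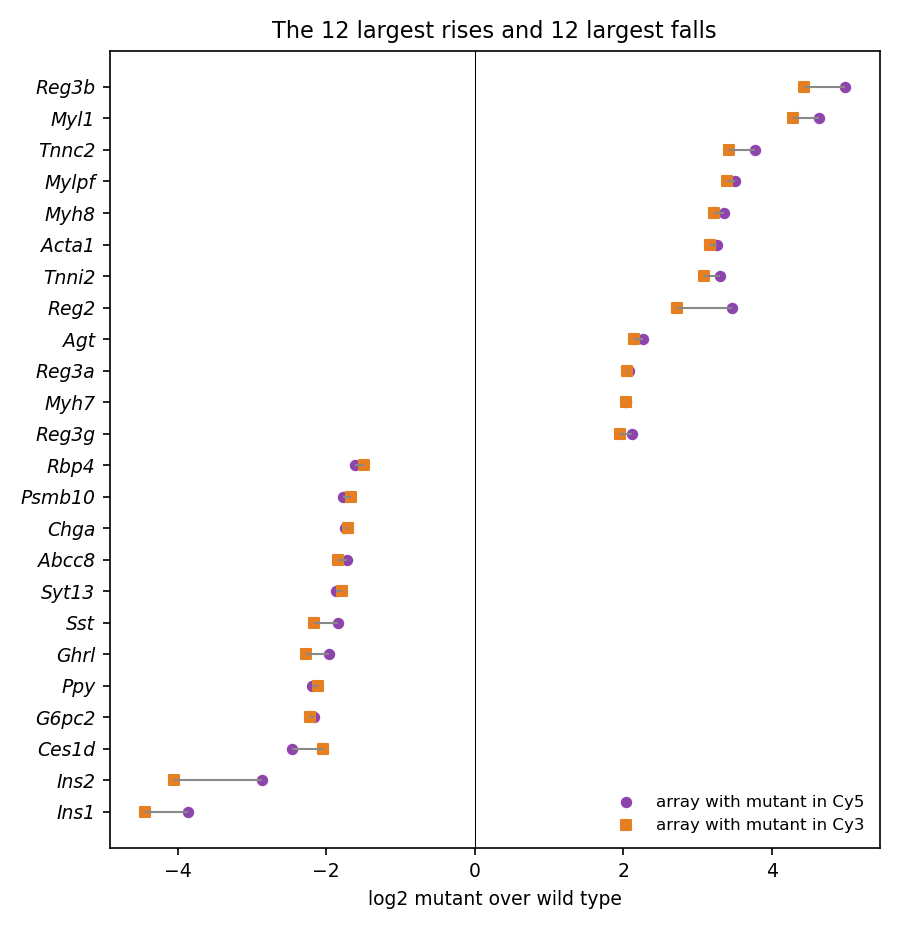
Log2 ratios of mutant over wild type on the array with the mutant in Cy5 (circles) and on the array with the mutant in Cy3 (squares) for the 12 genes with the largest mean rise and the 12 with the largest mean fall past the rule of size. The rises hold 4 regenerating protein genes and 7 genes of the skeletal muscle list, and the falls are led by Ins1 and Ins2, whose wild-type signals were saturated on 1 and 2 arrays.

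Exocrine genes differed one by one. Many genes of acinar cells were beyond the range of the scanner: 12 of 26 detected acinar genes, among them Cpa1, Cel, Prss2 and Clps, were saturated in both genotypes on both arrays and give no ratio. Over the other 14 the median was -0.06, above 16.2% of random lists. With the mutant in Cy3 alone this median was 0.00. Gp2, the major membrane protein of zymogen granules, was 3.81-fold higher, and Ctrl, a chymotrypsin-like protease, was 2.16-fold lower. Psmb10, its neighbour on chromosome 8 and outside the list, was 3.31-fold lower. The other 12 acinar genes did not pass. Of 19 duct genes none passed, with a median of 0.05. Onecut1, a transcription factor of duct cells, had a ratio of 0.89 and Tff2 0.50.

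The regenerating protein genes, which encode secreted lectin-like proteins of exocrine pancreas and gut, were higher. Of 7 measured members, 4 passed the rule. Reg3b (NM_011036) rose the most of all named genes and was 26.1-fold higher, with ratios of 4.98 and 4.43. Reg2 was 8.56-fold higher, Reg3a 4.18-fold and Reg3g 4.10-fold. Reg3d had a ratio of -0.18 and Reg4 0.07. Reg1 was saturated in the mutant on both arrays and in the wild type on 1, so no change is reported for it. The median of the list was 2.04, above all 10000 random lists. In the same comparison the skeletal muscle, myeloid and mesenchyme lists, at 0.93, 0.23 and 0.16, were also above all of them.

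Genes of skeletal muscle, a tissue outside the pancreas, were higher in the mutant pool. Among the 12 largest rises were the myosin light chain genes Myl1, 22.0-fold higher, and Mylpf, 11-fold higher, and the troponin genes Tnnc2, 12.1-fold higher, and Tnni2, 9.14-fold higher. The myosin heavy chain genes Myh8, 9.75-fold higher, and Myh7, 4.10-fold higher, and the skeletal actin gene Acta1, 9.29-fold higher, were also among them. A further probe described as myosin light polypeptide 1, without a gene name here, had a ratio of 1.03, and the other detected probe of Myh8 had 0.06. In the list of skeletal muscle genes drawn up after these rises were seen, 23 of 51 detected members passed the rule, all higher, and 45 were above 0 on both arrays. The median was 0.93, above all 10000 random lists. This list was made because of the rises and is not independent evidence of them. The lists of cardiac and smooth muscle genes, drawn up at the same time, had medians of -0.01 and -0.02 and means of 0.02 and 0.01. No member of either passed. Tnnt2, at 0.41, was well above background in the wild type on only 1 array, with mean raw signals of 92.8 in the mutant and 76.2 in the wild type. Tagln had 0.23 and, by its other detected probe, -0.13.

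Markers of other cell types moved by less. None of 13 endothelial genes passed, their median was -0.22, below all random lists, and 10 were below 0 on both arrays; Flt1 had -0.55 and Egfl7 -0.42. The myeloid median was 0.23, above all random lists, with the lysozyme genes Lyz2 at 0.86 (0.48 by its other detected probe) and Lyz1 at 0.85. The mesenchyme and matrix median was 0.16, also above all random lists, with Des at 0.64 and Pdgfra at 0.45 (0.04 by its other detected probe). Of its 19 members, 11 were above 0 and 2 below 0 on both arrays, and the others changed sign, such as Col1a1 (0.49 and -0.11) and Vim (0.23 and -0.18). The lymphoid median was 0.11, with Cd52 at 0.64 and Cd74 at 0.41. No member of these lists passed the rule. With the mutant in Cy3 alone the myeloid median was 0.14, the mesenchyme and matrix median 0.07 and the lymphoid median 0.17. The liver median was 0.09 (Alb 0.42, Ahsg 0.18), the adipocyte median 0.05 (Car3 0.89, Cidea -0.20), the intestine median 0.03 (Vil1 -0.18, Fabp2 0.16, and -0.16 by its other detected probe), the erythroid median 0.01 with a mean of -0.04 (Hba-a1 -0.46, Alas2 -0.26) and the neuron and Schwann cell median -0.06 (Elavl4 -0.54, and -0.15 by its other detected probe, S100b -0.42). The Y-linked genes and Xist had a median of 0.01 and a mean of -0.04, with Eif2s3y at -0.27 and Xist at 0.03. Reference genes had a median of 0.02, and B2m, at 0.58, and Gapdh, at 0.35, had the largest ratios among them. The reference median was -0.05 under median centring.

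**Figure D3:**
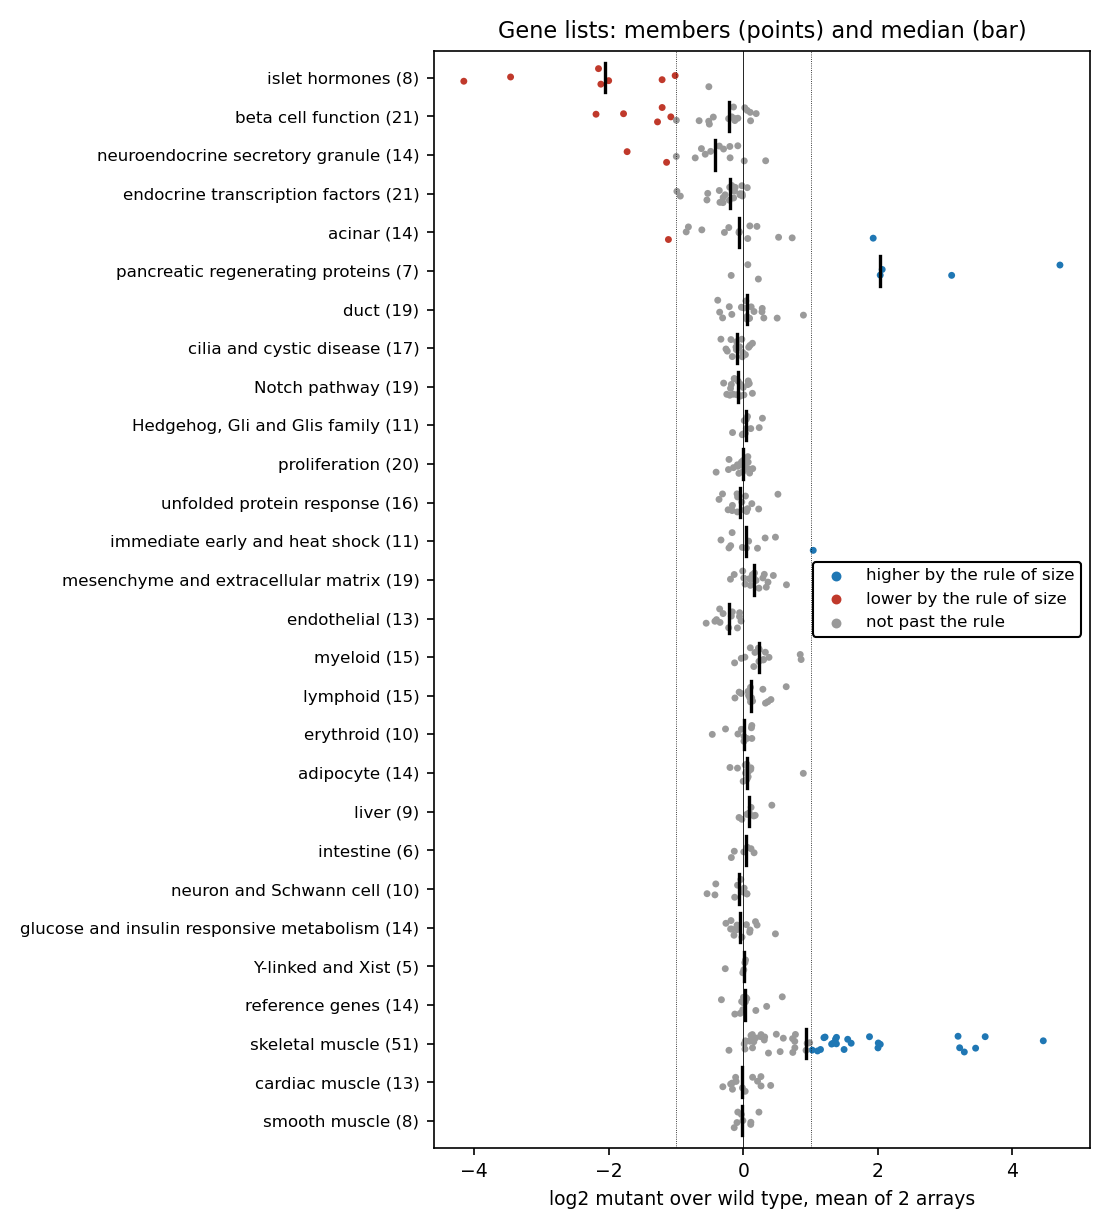
Each row is a gene list, with its number of members used, and each point is a member's log2 ratio of mutant over wild type, as the mean of 2 arrays. Black bars are medians, dotted lines mark 2-fold, and colours mark members past the rule of size. The islet hormones lie furthest to the left, with a median of -2.06, and the regenerating proteins furthest to the right, with a median of 2.04. The muscle lists were drawn up once the rises had been seen.

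The medians of signalling and stress lists were small. The median was -0.09 for cilia and cystic disease genes (Ofd1 -0.33, Bicc1 -0.26), -0.08 for the Notch pathway (Nrarp -0.29, Jag2 -0.25), 0.04 for the Hedgehog, Gli and Glis genes (Boc 0.28, Smo 0.24, and -0.07 by its other detected probe) and -0.01 for proliferation genes (Rrm2 -0.40, Tyms -0.22). It was -0.05 for the unfolded protein response (Chac1 0.51, Sdf2l1 -0.36) and -0.06 for genes of metabolism that respond to glucose and insulin (Txnip 0.48, Acly -0.26). No member of these 6 lists passed the rule. The cilia median was above 0.42% and the Notch median above 0.56% of random lists, with 11 of 17 and 10 of 19 members below 0 on both arrays. Among immediate early and heat shock genes the median was 0.05 (-0.07 with the mutant in Cy5 alone), and Fos, 2.06-fold higher, was the 1 member that passed.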

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

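All tests of explanations in this part were chosen after the results were seen. Among probes without a gene name here, which are in no gene list, 17 of 16051 well above background passed the rule of size, 8 higher and 9 lower in the mutant pool. Several of those that rose are described in the files as muscle transcripts, among them a tropomyosin 2 clone with a ratio of 3.33 a predicted adult skeletal myosin heavy chain with 1.66 and a cardiac triadin isoform with 1.04. The probes named as Tpm2, the tropomyosin 2 gene, had 0.23 and 0.37. Among those that fell, a clone described as a Pax6 product had -1.39, while the probe used for Pax6 had -0.30. These probes were named after their values were seen.

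Whether the rise of skeletal muscle genes comes from skeletal muscle RNA in the mutant pool is left open: the list's median of 0.93 decides nothing, because the list was drawn up after the rises were seen. The heart and smooth muscle lists had medians of -0.013 and -0.018, although the cardiac triadin probe rose. They were drawn up at the same time, so risen genes could be placed in the skeletal list instead. Their medians therefore do not decide whether heart or smooth muscle was a main source. The tables do not show whether muscle came in during dissection, in 1 pup or both, or belongs to the mutant tissue. The genotype was not tested as an explanation, because each pool is a single sample.

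For the fall of islet hormone genes, dilution of pancreatic RNA by other RNA as the whole cause is argued against by acinar genes. The 13 acinar genes without a saturated spot had a median of -0.063, against -2.06 for the hormones. That acinar median lay between -0.62 and 0.20 in 95% of random resamplings of these genes. This range describes the spread among the genes and leaves out differences between pups. The single ratios of the 13 genes ran from -1.11 (Ctrl) to 1.93 (Gp2). Dye bias is argued against because 0 of the 8 hormone genes changed sign between the dye orientations. An equal loss of all endocrine cells as the whole cause is left open. The ratios of the 6 genes without a saturated spot had an SD of 0.69, against a technical SD of at most 0.104 at the hormone genes' intensity. With the mutant in Cy5, where Ins1 was not saturated, its ratio was -3.87 and that of Iapp -0.66. The falls in these pools were thus unequal beyond array noise, but differences between pups were not measured to set this against. Unequal losses of the islet cell types, lower expression per cell, and differences between pups or litters stay open. The Glis3 genotype stays among the open explanations and was not tested, with 1 pool each.

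Intestinal RNA carries transcripts of the regenerating protein family. It is argued against as the source of their rise, but only by 6 detected genes of 11 listed. These had a median of 0.033 (-0.06 with the mutant in Cy5 alone and 0.16 in Cy3 alone), against 2.04 for the regenerating proteins. Cross-hybridisation between related transcripts may add to the rise of some members, and it cannot be told apart from separate rises here because probe sequences were not analysed here. Reg3d, a member of the family, had a ratio of -0.18, which excludes nothing for the others. The genotype and differences between pups stay open and untested.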

How the results depend on the processing

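The filter on negative controls and the count without skeletal muscle genes were chosen after seeing the data. With the software's own ratios, and with the deposited series table that holds them, 50 genes were higher and 44 lower, and with a normexp offset of 0 it was 49 and 42, against 38 and 25; all 63 called genes were among them. An offset of 0 does not shrink dim ratios, and the cause was not otherwise tested. By construction, a 3-fold rule left 19 higher and 11 lower, and a 1.5-fold rule gave 75 and 67. Leaving out the skeletal muscle list left 15 higher. With either array alone, 42 genes were higher and 32 to 33 lower. With the mutant in Cy5 alone Pcsk2 and Pyy, and with it in Cy3 alone Cltrn, fell short of 2-fold. Without saturated probes, Ins1 and Ins2 dropped out by construction, and the median over probes ended the calls of Abcc8, Pcsk2, Ppp1r1a, Pyy, Syt13 and Sln. Loess followed by Aquantile leaves ratios as they are and tests nothing.

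The hormone median ranged from -2.14 to -1.60, that of beta cell function from -0.33 to -0.21 and that of the regenerating proteins from 1.96 to 2.66. Of the 25 lists fixed before the data were examined, 18 kept the sign of their median under all 13 alternatives and 7 with medians near 0 did not. The correlation of the arrays ranged from 0.64 to 0.74. No called gene changed direction. Of the ratios of named genes under alternatives, 150 moved by more than the SD between arrays and 1302 did not. Filters on dim probes and the Aquantile step leave a gene's ratio as it is, and the series table repeats the software's ratios. Ratios under such alternatives could not move or were counted again, so these counts do not measure robustness. No paired analysis was possible because each genotype is 1 pooled sample and the result comes from no test. Saturation limits the acinar and insulin genes, and signals near the negative controls limit falls of dim genes such as Mafa.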

Other observations

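The tests in this part were chosen after the results were seen. Outside the lists, the 12 largest falls also held Ces1d, a carboxylesterase gene, 4.77-fold lower, Syt13, a synaptotagmin gene, 3.55-fold lower, Psmb10, which encodes an immunoproteasome subunit, 3.31-fold lower, and Rbp4, the retinol binding protein gene, 2.93-fold lower. The other detected probe of Syt13 had a ratio of 0.03, and that of Ppp1r1a, named below, -0.32. The 12 largest rises also held Agt, the angiotensinogen gene, 4.62-fold higher. Further genes past the rule, named after their values were seen, were higher in the mutant pool: Onecut2, a relative of Onecut1, 3.45-fold, St8sia3, a sialyltransferase gene, 3.47-fold (its probes ranged from 0.37 to 2.09), Inhba, the activin subunit gene, 2.70-fold, Krt20, a keratin gene, 2.60-fold, Gc, the vitamin D binding protein gene, 2.59-fold, and Scx, a transcription factor gene of tendon, 2.31-fold. Among further genes that were lower, Ppp1r1a, a phosphatase inhibitor gene, was 2.60-fold lower, Slc2a5, the fructose transporter gene, 2.62-fold and Celf3, an RNA binding protein gene, 2.24-fold.

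Some called genes lie side by side in the genome. In the gene order of assembly GRCm38.p6, restricted to detected genes, 5 neighbouring pairs were called in the same direction, while 2000 shuffles of the calls over the genes gave a mean of 0.127 pairs, and none gave 5 or more. Among the pairs are Myh4 and Myh8, Ppy and Pyy, and Reg3a and Reg2, which are related in sequence. St8sia3 and Onecut2 on chromosome 18 had ratios of 1.79 and 1.79, and Ctrl and Psmb10 on chromosome 8 had ratios of -1.11 and -1.73. The members of these last pairs belong to different gene families. The shuffles treat related genes as independent, and the 2 unrelated pairs alone are a number reached in 13 of the 2000 shuffles. These 2 were picked out of the 5 once seen, so that count does not measure how rare they are. The strain of the pups at these positions is not given in the sources used here, and no explanation for these pairs was tested.

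At the top of the intensity range, acinar genes saturated in both genotypes read 0.00 on the array with the mutant in Cy5 and 0.33 on the other, for example Cpa1. The mean raw signal of Cpa1 was 65310.6 in both genotypes, so the 0.33 arose in processing and is not a measured change. Whether bright unsaturated genes carry a like shift on that array was not tested.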
